A study of Bifidobacterium breve UCC2003 with 4 samples.

How the data were processed

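Total RNA from cultures of Bifidobacterium breve UCC2003 was hybridised in pairs to 4 two-colour Agilent arrays. Per the labels, the medium was a modified MRS broth with 0.05% cysteine-HCl and the sugars named for each culture, and RNA isolation and labelling followed an earlier protocol. The ribose culture was in Cy3 on ribose replicate 1 and in Cy5 on ribose replicate 2, and the mixed-sugar culture was in Cy3 on its replicate 1 and in Cy5 on its replicate 2. Replicate numbers follow the order of deposit and pair no arrays.

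The deposited scanner files hold spot and background intensity for each channel, read from the scans with Agilent Feature Extraction 9.5 per the labels, and version 9.5.1.1 per the file headers of 3 of the 4 arrays. The file of mixed-medium replicate 1 lacked the settings block and gave values to about 3 significant digits. Processed intensity in the same files was background-subtracted and dye-normalised by that software, per the file headers. The deposited log10 ratios in the scanner files are of Cy5 over Cy3 processed signal. The authors also deposited a value table in log10, which equalled those ratios within 0.005 after the sign was turned on the 2 arrays with the ribose-containing culture in Cy3, so its scale and direction were settled and no further centring was found. Its column medians were 0.00301, -0.0549, -0.00533 and -0.00387 for ribose replicates 1 and 2 and mixed-medium replicates 1 and 2. The genome build behind the probes is not given in the sources used here.

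Each array had 10807 spots, of which 10263 were not controls. They held 5664 probes, 3 per feature, for 1888 named features, among them 1843 locus tags, 20 tRNA features and 1 ribosomal RNA. Of the probes, 4599 were spotted 2 times and 1065 once, and 9 probe sequences were duplicates of another, so their genes could not be told apart by them. The files name genes only by locus tag. The reference table of the species is of another strain, and 0 of 1843 tags matched it, so no gene symbol, function or coordinate was used here. For the same reason none of the 20 gene lists fixed before the data were examined could be tested, which covered ribose uptake, the pentose phosphate and bifid pathways, sugar transport, glycoside hydrolases, nucleotide and amino acid synthesis, ribosomal proteins, chaperones and others. The tRNA list was added afterwards.

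Background was corrected with normexp at an offset of 50 on mean spot and median background signals, and ratios were normalised within arrays by loess in limma 3.58.1 under R 4.3.3, with control spots and spots marked as outliers given no weight. Outlier spots numbered 86 and 3 on the ribose arrays and 63 and 28 on the mixed-medium arrays and were left out. Saturated spots, 0 on both ribose arrays and 6 on each mixed-medium array, were kept. Ratios were turned so that the ribose-containing culture stood over glucose, spots were averaged to probes and probes to genes, giving log2 ratios for 1864 genes computed from the deposited values. The filter on dim genes removed none. Log2 ratios of genes had an SD of 0.65 and 0.45 on the ribose arrays and 0.66 and 0.78 on the mixed-medium arrays, and the arrays correlated across genes with r = 0.48 within the ribose comparison and 0.87 within the mixed comparison.

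All 4 arrays entered 1 limma fit with moderated variances (2 residual degrees of freedom, prior degrees of freedom 4.45, prior SD 0.268), and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05, two-sided. Errors given as SD are between the 2 arrays, and SE comes from the fit. The median SE was 0.18 for each comparison with glucose and 0.26 for their difference. The tRNA list was tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. The rule fixed beforehand took the extreme genes that passed and kept their sign on both arrays. Since the tags carry no names, only the 2 highest and 2 lowest per comparison are named, plus runs of tags, tRNA features and some single tags chosen after their values were seen.

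The fit was tested on simulated data with 1864 genes. In the ribose comparison 12% of genes changed by a log2 ratio of 1 and 66% of those changed by 2 were recovered, with 1 false call among 1764 unchanged genes. In the mixed comparison 50% and 98% were recovered, with 6 false calls. Simulated noise came from the same fitted prior on every array, with 50 genes changed at each size in each comparison. In the data the SD between arrays was 0.41 on ribose and 0.28 in the mixed comparison. These figures therefore test the code and do not give the power or error rate of the real comparisons. Alternatives covered background correction, normalization, the value table, filters, probe summary, a dye term, each comparison alone, the variance prior, the threshold and the removal of each array. Turning the mixed-medium arrays was added after the data were examined. No slide or scan held more than 1 array, as far as the headers show, so no batch term could be fitted. Figures were drawn with matplotlib 3.10.9.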

Results

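Expression was measured in Bifidobacterium breve UCC2003, a commensal gut bacterium, on 4 two-colour arrays that each set a culture grown with ribose against a culture grown with glucose. On 2 arrays the medium of the first culture held 1% (w/v) ribose as its only added sugar. On the other 2 arrays it held 0.5% ribose with 0.5% glucose, called the mixed medium here. The opposite channel always held a culture on 1% glucose, and all cultures were harvested in exponential growth at an optical density of 0.5. Each comparison therefore had 2 arrays, of opposite dye orientation. The series design describes 2 biological replicates with a dye swap in 1 of them, and the sample titles mark the second array of each comparison as the swap. If a swapped array held the same RNA as its partner, each comparison would have 1 replicate, and SDs and p-values would measure technical spread only. Median net signal was 446 in Cy3 and 451 in Cy5 on ribose replicate 1, and 62.0 and 86.7 on ribose replicate 2, which was the dimmest array. It was 469 and 187 on mixed-medium replicate 1, and 557 and 1504 on mixed-medium replicate 2. Between 96.6% and 99.2% of spots were well above background in each channel, and the number of arrays limits the precision.

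The direction of the ratios could not be settled from the data. Per the dyes in the labels, a positive log2 ratio means more RNA in the ribose-containing culture than in the glucose culture, and the authors' deposited ratios run the same way. However, arrays of the same dye orientation from the 2 comparisons correlated negatively over spots, with r = -0.47 between the first replicates and r = -0.40 between the second replicates, although each sets a ribose-containing culture against glucose. Values below follow the labels, and those with the mixed-medium arrays turned are given beside each result. If instead the ribose arrays were the ones to turn, every sign in the ribose comparison would change, and the number of genes called in each comparison with glucose would stay as given.

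The first comparison asked how gene expression on ribose differed from that on glucose. A block of 5 genes with consecutive locus tags, Bbr_1415 to Bbr_1419, rose most, with a median log2 ratio of 3.49 and a range of 2.73 to 3.71. Within it, Bbr_1418 was 13.1-fold higher on ribose (log2 ratio 3.71 ± 0.50, SD, n = 2 arrays) and Bbr_1417 was 11.7-fold higher (3.55 ± 0.53, SD, n = 2). In the other direction, Bbr_0182 was 10.8-fold lower (log2 ratio -3.43 ± 0.93, SD, n = 2) and Bbr_0183, which bears the next tag, was 6.97-fold lower (-2.80 ± 0.07, SD, n = 2).

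In all, 17 of 1864 genes passed an adjusted p of 0.05 in limma, of which 6 rose and 11 fell on ribose. All 17 changed at least 2-fold, with the same sign on both arrays and on every probe. The adjusted p in limma was 0.0013 for Bbr_1418, Bbr_1417 and Bbr_0183, and 0.0048 for Bbr_0182. With the ribose arrays turned, the same values would read as 11 genes higher and 6 lower on ribose. The count rested on the pair of arrays, being 392 without replicate 2 and 96 without replicate 1, where the lone array was assumed to vary like those of the mixed medium, and median centring in place of loess gave 113 genes, with the balance turned to 95 higher and 18 lower.

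Genes next to the block did not follow it uniformly. Bbr_1420, the next tag, had a log2 ratio of -0.02 on ribose (limma adjusted p = 0.969), and Bbr_1421 rose by a log2 ratio of 1.94 (adjusted p = 0.024). The tags from Bbr_1422 to Bbr_1429 differed between the ribose arrays: Bbr_1425 had 0.45 on replicate 1 and 2.77 on replicate 2, and none of these tags passed the test. In the mixed medium the ratios of Bbr_1415 to Bbr_1419 lay between -1.60 and -2.27, and all 5 genes fell. With the mixed-medium arrays turned they would instead have risen by the same amounts.

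**Figure D1:**
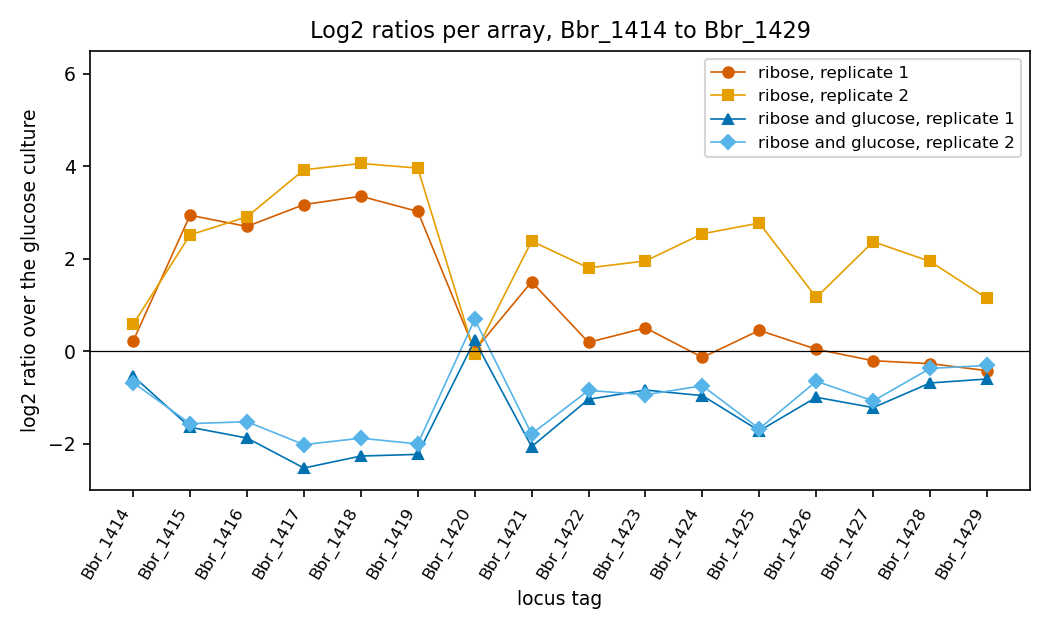
Log2 ratio of the ribose-containing culture over the glucose culture on each of the 4 arrays (vertical axis) for the locus tags from Bbr_1414 to Bbr_1429 (horizontal axis); each marker is 1 gene on 1 array and lines only join markers of an array. Bbr_1418 reads 3.35 and 4.06 on the ribose arrays and -2.27 and -1.88 on the mixed-medium arrays, as signed by the labels.

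The second comparison asked how expression with both sugars differed from that on glucose alone. Bbr_0691 was 8.41-fold higher in the mixed medium (log2 ratio 3.07 ± 0.24, SD, n = 2 arrays) and Bbr_1879 was 7.97-fold higher (2.99 ± 0.43, SD, n = 2). Bbr_1417 was 4.83-fold lower (log2 ratio -2.27 ± 0.36, SD, n = 2) and Bbr_1419 was 4.34-fold lower (-2.12 ± 0.16, SD, n = 2). With the sign turned, these read -3.07 for Bbr_0691, -2.99 for Bbr_1879, 2.27 for Bbr_1417 and 2.12 for Bbr_1419.

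Of 1864 genes, 605 passed in limma, of which 319 rose and 286 fell, or the reverse with the sign turned. At least a 2-fold change was seen in 249 of them, and all 605 had the same sign on both arrays. The adjusted p in limma was 0.0091 for Bbr_0691, 0.0013 for Bbr_1879, 0.0034 for Bbr_1417 and 0.0049 for Bbr_1419. The count fell to 3 without mixed-medium replicate 1 and to 19 without replicate 2, where the lone array was assumed to vary like the ribose arrays, and was 965 with either ribose array left out. Without replicate 1 the calls of Bbr_0691, Bbr_1417 and Bbr_1419 ended (adjusted p = 0.0676, 0.0582 and 0.0635), and without replicate 2 those of Bbr_0691 and Bbr_1419 (0.113 and 0.06), with folds about as large. Median centring gave 1044 genes, and the Feature Extraction software's own processed signals gave 283.

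Genes that changed in the mixed medium lay next to each other more often than when tags were shuffled. There were 58 runs of at least 3 consecutive tags called in the same direction, holding 239 of the 600 called tags (39.8%), against a mean of 12.5 runs and a highest number of 26 when the tags were shuffled 10000 times (p = 1e-04, permutation, one-sided, the smallest these shuffles can give). Of the runs, 34 rose and 24 fell. The longest were the 11 genes from Bbr_0113 to Bbr_0123, which rose with a median log2 ratio of 0.81, and the 11 genes from Bbr_1009 to Bbr_1019, which fell with a median of -1.03. The 8 genes from Bbr_0434 to Bbr_0441 fell with a median of -1.72, and the 5 genes from Bbr_1892 to Bbr_1896 rose with a median of 2.29. On ribose alone the only such run was Bbr_1415 to Bbr_1419 (p = 4e-04, same permutation). Across neighbouring pairs of tags, log2 ratios correlated with r = 0.57 on ribose and r = 0.53 in the mixed medium, over 1778 pairs of genes that are not independent replicates. Each run takes the opposite direction if its comparison is turned. Shuffling also removes the trend of the ratios along all locus tags that is described below. Set against shuffled tags, the number of runs and the neighbour correlations therefore do not separate local grouping from that trend. The run from Bbr_1415 to Bbr_1419 had ratios of 2.73 to 3.71 on ribose, against 0.40 for Bbr_1414 and -0.02 for Bbr_1420. For this run, such steps argue against a gradual trend as the source.

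The third comparison set ribose against the mixed medium, indirectly, as the difference between both log2 ratios to glucose. Bbr_1417 differed by 5.82 ± 0.34 (SE, 2 arrays per comparison) and Bbr_1418 by 5.78 ± 0.32 (SE), both higher on ribose. Bbr_1879 differed by -4.81 ± 0.29 (SE) and Bbr_0691 by -4.78 ± 0.67 (SE), both lower on ribose, although the ratio of Bbr_0691 to glucose on ribose, -1.71, did not pass its own test (limma adjusted p = 0.181). In limma, 658 genes differed, 309 higher and 349 lower on ribose, and 510 of them by at least 2-fold. These differences stand for ribose against the mixed medium only if the glucose cultures of both comparisons were alike, which is not settled here.

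With the mixed-medium arrays turned, the third comparison changed most. Only 4 genes then differed in limma, all higher on ribose, namely Bbr_0104 by 2.66, Bbr_0579 by 2.53, Bbr_1590 by 2.05 and Bbr_1894 by 2.35 on the log2 scale. These 4 were named after their values were seen. The turned differences of Bbr_1417 and Bbr_1418 were 1.28 and 1.63, with adjusted p of 0.151 and 0.0971, and those of Bbr_1879 and Bbr_0691 were 1.18 and 1.36, with adjusted p of 0.127 and 0.354. As signed by the labels, the count was 193 without mixed-medium replicate 1 and 47 without replicate 2.

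The genes that changed on ribose went mostly the opposite way in the mixed medium. All 6 genes that rose on ribose fell in the mixed medium, where independent lists would share 0.92, and 10 of the 11 that fell on ribose rose there, against 1.88. No gene rose in both or fell in both, where independent lists would share 1.03 and 1.69. Since 1 fit gave each gene the same SE in both comparisons, the lists are not independent, and these expected numbers are only a rough guide. Across 1864 genes, which are not independent replicates, the log2 ratios correlated with Pearson's r = -0.60 and Spearman's rho = -0.64, and 24.9% of genes had the same sign. With the mixed-medium arrays turned, r is 0.60, 75.1% of genes have the same sign, and the same calls read as 6 genes that rose in both and 10 that fell in both, against the same 0.92 and 1.88. Whether both comparisons used the same glucose RNA is not stated in the sources used here. Simulated unchanged groups against shared glucose RNA gave r = 0.50 and a covariance of 0.022, against an observed covariance of -0.197, and with 2 arrays per comparison the controls could not be split.

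**Figure D2:**
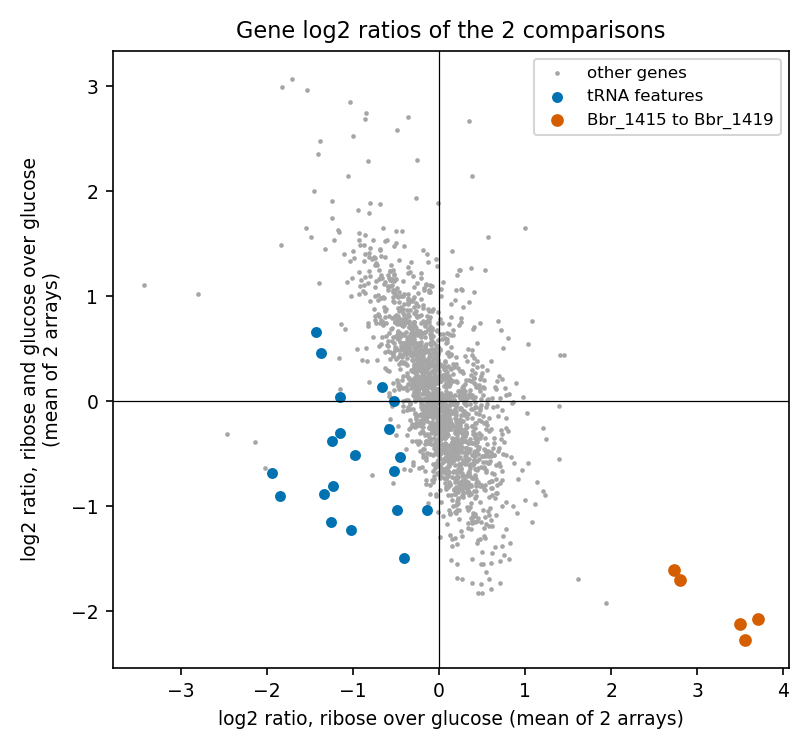
Mean log2 ratio of each gene over 2 arrays for ribose over glucose (horizontal axis) and for ribose and glucose over glucose (vertical axis), as signed by the labels; each point is 1 gene, with Bbr_1415 to Bbr_1419 and the tRNA features in colour. The points run from upper left to lower right (r = -0.60 across genes), and the 20 tRNA features all lie left of 0.

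The 20 tRNA features, which carry amino acids to the ribosome, had negative mean log2 ratios in both comparisons as signed by the labels, -0.99 on ribose and -0.53 in the mixed medium. Neither held as a call with an estimated correlation between the features (adjusted p = 0.519 and 0.651). On ribose all 20 had a negative log2 ratio, with a median of -1.09 and a range of -1.94 for tRNA-Gln to -0.14 for tRNA-Pro. None passed over all genes in limma, while 14 had an unadjusted p below 0.05 and 14 passed adjusted over the list alone, a list drawn from the names in the files after they were opened. Against the other genes, camera with its preset correlation gave an adjusted p of 1.15e-08 over 3 comparisons, and 0.519 with an estimated correlation. Fry, which sets the list against no change and not against other genes, gave an adjusted p of 0.315. The array medians were -1.48 and -0.34, and the mean was -0.45 without replicate 1 and -1.52 without replicate 2.

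In the mixed medium 16 of the 20 tRNA features were negative, 4 were positive with a highest value of 0.66, and 4 of the negative ones fell, namely tRNA-Met by a log2 ratio of -1.49, tRNA-Phe by -1.23, tRNA-Pro by -1.03 and tRNA-Thr by -1.04. There, 3 passed adjusted over the list alone. Camera gave an adjusted p of 0.00874 for a mean log2 ratio of -0.53 (-1.35 under median centring), and with an estimated correlation the adjusted p was 0.651. The list was not found to differ between ribose and the mixed medium (mean difference -0.46, camera adjusted p = 0.283), but this rested on single arrays: it was -0.99 without ribose replicate 2 (adjusted p = 0.00155) and 0.075 without ribose replicate 1. Under median centring it was 0.69. With the mixed-medium arrays turned, their mean was 0.53 and the difference -1.51 (camera adjusted p = 6.33e-12), a call lost with an estimated correlation (p = 0.131, unadjusted). The feature named for 16S ribosomal RNA had log2 ratios of 0.85 and 0.10 on the ribose arrays, which did not pass (limma adjusted p = 0.339). It fell in the mixed medium, with -0.95 and -1.67 on its arrays (adjusted p = 0.0165), or rose by as much with the sign turned. Its mean log2 brightness was 8.87, and that of the tRNA features ran from 8.15 to 12.1. Whether this feature measures the amount of 16S ribosomal RNA was not tested.

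**Figure D3:**
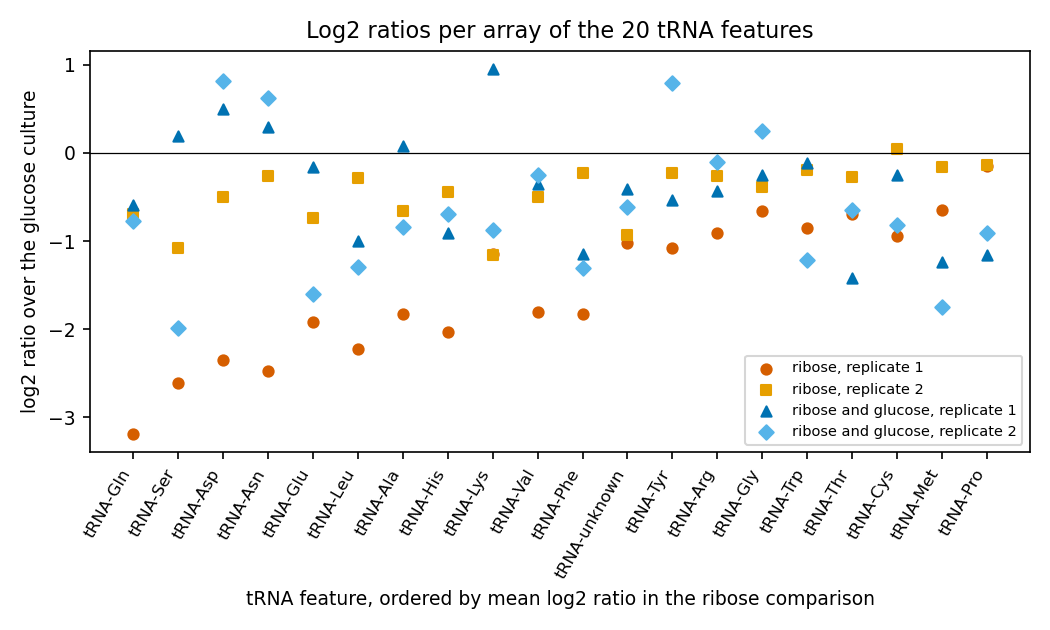
Log2 ratio of the ribose-containing culture over the glucose culture on each of the 4 arrays (vertical axis) for the 20 tRNA features (horizontal axis, ordered by their mean in the ribose comparison); each marker is 1 feature on 1 array, as signed by the labels. On ribose replicate 1 all 20 lie below 0, down to -3.19 for tRNA-Gln, and on ribose replicate 2 19 do.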

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

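The tests of label turning, dye bias, opposite responses and smaller changes on ribose were chosen after the result was seen, while that of the dim array was set beforehand.

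The 2 comparisons with glucose differed for 658 genes by the test of the difference in limma, among them all 7 genes named as extremes. The ribose minus mixed-medium log2 difference was 5.82 for Bbr_1417, 5.78 for Bbr_1418 and 5.61 for Bbr_1419, and -4.81 for Bbr_1879, -4.78 for Bbr_0691, -4.54 for Bbr_0182 and -3.82 for Bbr_0183. With the mixed-medium arrays turned the count was 4 and none of these 7 passed. The turned differences were -2.32 for Bbr_0182 (adjusted p = 0.0935), -1.78 for Bbr_0183 (0.0592) and 1.38 for Bbr_1419 (0.137), and 1.18 to 1.63 for the other 4.

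The ratios of the 2 comparisons ran opposite across genes. Dye bias left after loess and alike on all arrays would cancel in the mean of each comparison, which holds both dye orientations. Such bias could therefore not make the comparisons run opposite. Arrays of opposite dye orientation correlated positively within each comparison once turned, with a lower value of 0.482. That value does not show that no dye bias was left. Opposite responses to ribose alone and to the mixture from a common glucose state stay open. The glucose channels of the 2 comparisons differed more from each other than from the ribose-containing channels in all 4 array pairs, by an SD margin of at least 0.094. They also differed more than replicate glucose channels, with an SD of 0.94 to 1.09 against at most 0.84 once dye means were removed. As measured, the SD was 1.03 to 1.09 against at most 0.98. However, replicate glucose channels within the ribose comparison differed about as much as glucose from ribose across its arrays. Their SD was 0.84 once dye means were removed and 0.98 as measured. The 2 pairs of a glucose with a ribose channel across these arrays had SDs of 0.91 and 1.07 under either setting. In the mixed comparison replicate glucose channels lay closer, with an SD of 0.47 once dye means were removed and 0.44 as measured. The 2 pairs of a glucose with a mixed-medium channel there had SDs of 0.87 and 1.09. Given the wide spread on ribose, the margins between the comparisons cannot decide the question. Labels of the cultures or dyes turned in 1 comparison may account for the pattern. Within each dye every glucose channel resembled the ribose-containing channel of the other comparison more than any like-labelled pair, by a margin in rho of at least 0.030. Ratios that correlate negatively already draw channels of unlike label together. This margin thus partly restates the pattern and is not separate support for turned labels. Turned labels, opposite responses and glucose cultures that themselves differed between the comparisons cannot be told apart. No array links the cultures of one comparison to those of the other.

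Fewer genes passed on ribose (17) than in the mixed medium (605). Smaller changes in the ribose comparison may account for part of this. The SD of the change shared by both arrays was 0.56 times that of the mixed comparison, and 0.58 times with the software's processed signals. That shared SD includes the dim second ribose array. In the dimmest of 3 equal groups of genes its ratios had an SD of 0.21, against 0.47 on the first ribose array. The ratio of shared SDs therefore does not separate smaller changes from the dim array. The dim second ribose array stays open. The ribose arrays correlated with r = 0.58 in the brightest of 3 equal groups of genes, 0.35 in the middle and 0.41 in the dimmest. Agreement was thus neither clearly restored nor flat, and it did not rise steadily with brightness. The spread between arrays was wider on ribose, with an SD of 0.41 against 0.28. The fit gave each gene the same SE in both comparisons, so this spread does not account for the lower count on ribose.

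Some probes outside the comparisons gave signal above every negative control spot in all 8 channels. On ribose replicate 1 in Cy5, where the highest negative control reached 13.8, the net signal was 63.9 for pB21a-orf5, 238 for RNASPIKE3 and 471 for the feature named CDS. Of the 15 features with plasmid names, 12 were above the negative controls in no channel.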

How the results depend on the processing

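Turning the mixed-medium arrays was chosen after the data were seen; the other settings were fixed beforehand. The cause was not tested unless given. The counts for ribose, the mixed medium and their difference were 17, 605 and 658. They were 113, 1044 and 1099 under median centring, 11, 283 and 426 with the software's processed signals, 11, 286 and 428 with the deposited table, 32, 1589 and 1712 over probes, which are more numerous, and 11, 45 and 119 at an unadjusted p of 0.001 with 3-fold, a stricter threshold. Ribose gave 27 without background correction, and the mixed medium 965 when fitted alone. The ribose split of 6 higher and 11 lower became 95 and 18 under median centring, 6 and 5 with processed signals or the deposited table. Leaving out 1 array gave 12 to 392 genes on ribose, 3 to 965 in the mixed medium and 47 to 916 for the difference, with fewer arrays and a borrowed spread. The correlation of the comparisons was -0.71 under median centring and -0.61 to -0.46 with 1 array left out. The tRNA means on ribose (-0.99) and in the mixed medium (-0.53) kept their sign unless the arrays were turned, at -0.67 and -1.35 under median centring and from -1.52 to -0.45 and -0.66 to -0.40 with 1 array left out, and lost their call with an estimated correlation, which allows for members that vary together. Their difference was 0.69 under median centring and -0.99 to 0.075 with 1 array left out, being 0.075 without ribose replicate 1 and -0.99, past the threshold, without replicate 2. With the mixed-medium arrays turned, by construction, the difference gave 4 genes, the correlation 0.60, the mixed tRNA mean 0.53 and its difference -1.51; in the mixed medium Bbr_0691 read -3.07, Bbr_1879 -2.99, Bbr_1417 2.27 and Bbr_1419 2.12, and the difference 1.18 for Bbr_1879 and 1.36 for Bbr_0691. Of the other values of named genes that could move, 159 kept direction and side of the threshold and 7 lost the call with the same sign: in the mixed medium Bbr_0691 and Bbr_1419 without either of its arrays in turn and Bbr_1417 without replicate 1, and for the turned difference Bbr_1417 and Bbr_1418. Aquantile and the absence of a filter moved no ratio, say nothing of stability and are not counted. Each comparison alone gave no difference, and no slide or scan block could be fitted. No paired analysis was possible because replicate numbers follow the order of deposit only; the dye term, which parts the arrays by number too, gave 14, 875 and 907 genes. Ribose replicate 2 had the lowest net signal (62.0 and 86.7), with 98.2% and 96.6% of spots well above background.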

Other observations

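All tests of this part were chosen after the trend was seen.

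Log2 ratios followed the order of locus tags. In the mixed medium, the 461 tags nearest the start or end of the numbering averaged 0.57 ± 0.65 (SD over genes) and the 460 farthest averaged -0.29 ± 0.57 (SD). On ribose the means were -0.26 ± 0.47 and 0.10 ± 0.34. Spearman's rho with distance from the first tag, counted around a circle, was -0.42 and -0.51 on the mixed-medium arrays and 0.28 and 0.29 on the ribose arrays, all over genes, which are not independent replicates. Of 1842 rotations of the tag order, 59 gave as strong a rho for the mean of the mixed-medium arrays and 43 for that of the ribose arrays. For single arrays, 49 and 63 did so in the mixed medium, and 105 and 18 on ribose replicates 1 and 2. With the sign of a comparison turned, its trend turns as well.

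A gradient of gene dosage from a replication origin near the first tag, as arises when cultures replicate at different rates, may underlie this trend. It needs the trend on both sides of the numbering, and the weaker side had a rho of -0.45 in the mixed medium. Brightness of the genes is argued against for the mixed medium only. Its median-centred ratios, which had no loess, were split into 10 groups of genes of like brightness. There rho was negative in all 10, with a median of -0.47 and a range of -0.69 to -0.12. Brightness was not tested in this way on ribose. Over all genes, median centring weakened rho in the mixed medium to -0.28, with -0.24 on the weaker side. On ribose it weakened rho from 0.32 to 0.17. That tags follow the chromosome from its origin was assumed, and growth rates were not analysed here. The trend does not carry the opposition of the comparisons, whose correlation over locus tags was -0.64 before and -0.58 after distance was removed.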
